A study of Triticum aestivum with 9 samples.

How the data were processed

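Poly(A) RNA from wheat seed was sequenced as paired-end reads on an Illumina HiSeq instrument, per the labels' protocols. The labels give 3 libraries each for strong, medium and weak gluten wheat, bought from a pair of seed and breeding institutes in Henan, and name no cultivar, growing season, seed stage or batch. Per the labels' protocols the total RNA passed a quality minimum, and the same text speaks of an adipose type, words that do not match a seed sample. Samples were grouped by the gluten class in their own labels, and replicate numbers were taken from their titles.

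The authors deposited 1 table per library with FPKM per gene, fragments per kilobase of transcript scaled to the mapped fragments of the library, rounded to hundredths per the files. HISAT, an aligner, and StringTie, which assembles and quantifies transcripts, are named in the submitters' processing notes without versions. The genome build is not given in the sources used here; gene names in the files carry scaffold and chromosome arm names of the TGACv1 wheat assembly, and no coordinates are printed. Each table lists the same 105586 genes, of which 66113 are loci numbered by the assembly step and 16002 carry no gene name. The files describe 12090 genes, 5773 of them among the genes tested (14.4%), so counts of named groups cover a small part of the genes. Of 89584 gene names in the files 80 matched the supplied RefSeq table, so names and descriptions were taken from the files alone. FPKM keeps no read totals and low values showed no recoverable steps of whole reads, so depth is unknown and no counting interval was computed. Genes shared between near-identical copies, among them gliadins and the A, B and D copies of wheat genes, depend on how reads were divided before deposit.

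FPKM values were used as deposited, as log2(FPKM + 1), for the 40185 genes with at least 1 FPKM in at least 3 of the 9 libraries. Linear models of limma 3.58.1 in R 4.3.3, with class as the only term, all 9 libraries in one fit (6 residual degrees of freedom) and an intensity trend in the empirical Bayes step, gave the 3 pairwise comparisons. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested are called. Genes apart in a class are those called in the same direction against both other classes. Counts from 20 sets of simulated unchanged libraries and the product of list sizes over the genes tested are given beside them. Graded genes are those called between strong and weak seed whose medium mean lies between the other means. Silent genes have at most 0.1 FPKM in every library of a class and at least 1 FPKM in every library of the others, and were compared between chromosome arms by Fisher's exact test, two-sided, adjusted over arms and classes. Summed FPKM of gliadin and glutenin genes was compared by an exact two-sided permutation test of log2(sum + 1), which with 3 against 3 libraries cannot go below 0.1.

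Before the data were examined, 26 gene lists were fixed as word patterns searched in names and descriptions. They were high molecular weight glutenin, LMW glutenin, alpha, gamma and omega gliadin, avenin-like proteins, globulins, puroindoline and grain softness proteins, amylase/trypsin inhibitors, serpins, starch synthesis, sucrose cleavage and sugar transport, protein folding in the endoplasmic reticulum, nitrogen assimilation, storage protein regulators, photosynthesis, embryo and oil body, dehydrins, aleurone and germination, lipid transfer proteins, heat shock proteins, cell cycle and histones, ribosomal proteins, redox, defence and root or vegetative shoot. The 18 lists with at least 5 tested genes were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over lists, with camera at an estimated correlation and fry beside it. No list call held with the estimated correlation or with fry. At the preset correlation most regroupings of the same libraries called as many lists. No gene in the files matched the patterns for high molecular weight glutenin or omega gliadin; avenin-like, puroindoline and storage protein regulator patterns matched 1 gene each, not tested; globulins and amylase/trypsin inhibitors had 1 tested gene each and serpins 3. The word thionin also matches enzymes of methionine, so the defence list holds 49 tested genes of which 13 are left without them.

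Genes named in the text follow a rule fixed before the data were examined. For each comparison it takes, among called genes with non-overlapping libraries, a mean of at least 5 FPKM in the higher class and an informative description, the 6 with the highest and the 6 with the lowest log2 fold change. From each list it takes the 2 tested genes with the highest mean and the called gene with the largest absolute change, and for each class the 3 silent genes with the highest mean elsewhere. The text names part of these, a choice made with the values known.

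The method was tested on simulated data made from the real libraries, with 50 genes changed at each size. These were drawn only from genes averaging about 5 FPKM or more on the log2 scale, so recovery of lower genes was not measured. At log2 changes of 1, 2, 3 and 4 it called 6%, 70%, 90% and 90% for strong against weak, 0%, 58%, 94% and 98% for strong against medium and 0%, 70%, 86% and 94% for medium against weak, all over 40185 genes. Of 39945 unchanged genes it called 7, 12 and 4, and camera called 0 of 20 random lists in each comparison and found the planted list. Simulated noise was independent between genes, so this does not show how often camera calls lists of correlated genes by chance. The correlation estimated in the real libraries was 0.706 for LMW glutenins and 0.418 for heat shock proteins.

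Alternatives fixed before the data were examined were a pseudocount of 0.1, no low-value filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, TPM made from FPKM, the replicate number as a block, robust empirical Bayes, only the classes compared, a log2 change of at least 1, other limits for silent genes and leaving out each library. Chosen after seeing the data were the same leave-outs with the genes tested kept, leaving out the second library of every class, leaving out genes listed at 0 in one library and at 5 FPKM or more in another of the same class, lists without wrong matches, a Gene Ontology (GO) list, the summed FPKM of gliadin and glutenin genes, and tests by chromosome arm and GO term. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the main results.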

Results

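Messenger RNA was measured in seed of hexaploid bread wheat (Triticum aestivum) of 3 gluten classes, strong, medium and weak, with 3 libraries per class and 9 in all. Gluten is the storage protein network that gives dough its strength, built mainly from gliadins and glutenins made in the starchy endosperm. The labels call the 3 libraries of a class biological repeats, without saying whether they came from separate plants, fields or seed lots, so the p-values measure the spread between these libraries. Cultivar, growing place and seed stage are not given in the sources used here, so class, genotype and growing place cannot be told apart in any comparison. The files give FPKM for 105586 genes and assembled loci, of which 40185 reached 1 FPKM in at least 3 libraries and were tested. The FPKM of a library summed to between 547450 and 623897, and between 31015 and 38492 genes had at least 1 FPKM. FPKM values keep no read totals, so the sequencing depth is unknown and no interval for counting error is given. Pearson correlations of log2 values across tested genes, which are not independent replicates, ran from 0.811 to 0.908 within classes and from 0.768 to 0.858 between them. Loci assembled by the authors that carry no gene name held between 30.1% and 54.3% of the FPKM of a library, and in each class the second library had the highest share. Of 2229 genes with at least 20 FPKM in at least 6 libraries, 65 were listed at 0 in another library, so a 0 is treated below as a listed value and not as proof of absence. Fold changes are differences of mean log2(FPKM + 1), which understate changes of low genes, and errors of fold changes are standard errors from limma. Gene identifiers are those of the files, and the chromosome arms are those written in the reference names that the files pair with them.

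**Figure D1:**
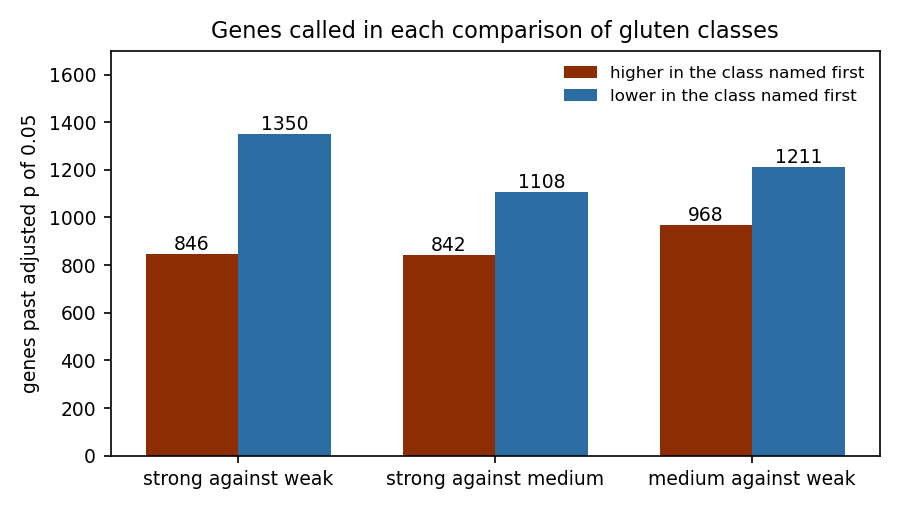
Number of genes past a limma adjusted p of 0.05 in each comparison of gluten classes (vertical axis, number of genes), with 3 libraries per class and 40185 genes tested. Dark bars count genes higher in the class named first and blue bars genes lower in it, and in each comparison the lower bar is the taller, from 1108 to 1350 genes.

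Strong against weak gluten was the widest contrast of the trait that the labels name. All 5 tested genes for low molecular weight (LMW) glutenins, which link glutenin polymers into gluten, and all 5 for gamma gliadins had a higher mean in strong seed, with median log2 differences of 3.07 and 2.29. Of these genes 1 and 0 were called, and both list calls were lost with an estimated correlation between genes and with fry. With a pseudocount of 0.1 the LMW glutenin median was 5.78. The antimicrobial peptide WAMP-1 (MSTRG.16330, arm 2DL) was abundant in strong seed, at 190, 179 and 286 FPKM, and near or at 0 in weak seed, at 0.02, 0 and 0 FPKM. In the other direction, the small GTPase RABC1 (MSTRG.12562, 2BL) averaged 0.0233 ± 0.0115 FPKM in strong and 17.0 ± 6.97 FPKM in weak seed (SD, n = 3). A stress-response A/B barrel protein HS1 (MSTRG.11385, 2AS) averaged 0.827 ± 0.264 and 26.2 ± 9.05 FPKM. In all, 846 genes were higher and 1350 lower in strong seed.

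Summed over the 23 gliadin and glutenin genes of the fixed lists, the strong libraries held 1219, 332 and 1106 FPKM, against 314, 29.2 and 84.9 FPKM in the weak libraries. On the log2 scale the totals differed by 3.03 ± 1.15 (SE), a fold of 8.19, with every strong library above every weak library (exact two-sided permutation test, p = 0.1, the smallest p that 3 against 3 libraries allow). The difference ran from 2.22 without weak replicate 2 to 3.91 without weak replicate 1. In each class the library with the lowest total was the second, which also had the highest share of FPKM in unnamed loci. Camera called the LMW glutenin list (adjusted p = 4.84e-05), with 1 of its 5 genes called over all genes and 4 adjusted over the list alone. With an estimated correlation between genes its adjusted p = 0.45. The gamma gliadin list was called as well (adjusted p = 0.0224), with 0 of 5 genes called over all genes and 1 adjusted over the list alone, and its adjusted p = 0.45 with an estimated correlation. Its call was lost under both other scalings of the libraries, with a pseudocount of 0.1 (adjusted p = 0.0611) and without weak replicate 2 or, with the same genes tested, strong replicate 1 (adjusted p = 0.0993 and 0.0958, and 0.136 at the highest). The called LMW glutenin gene, MSTRG.5989 on 1BS, had 15.4, 5.32 and 18.6 FPKM in strong seed and was listed at 0 in all weak libraries (limma adjusted p = 0.018). The more abundant glutenin subunit gene MSTRG.8204 (1DS), whose locus the files also describe as an LMW glutenin, stood at 123.4, 38.5 and 179 FPKM in strong seed and at 22.2, 2.19 and 0 FPKM in weak seed. It did not pass the test (limma adjusted p = 0.0623), but did so with quantile normalization and without weak replicate 1 or medium replicate 1, down to 0.0135. Gamma-gliadin 2 (MSTRG.8405, 1DS) averaged 137 ± 83.0 against 31.5 ± 35.6 FPKM (SD, n = 3) and did not pass (adjusted p = 0.283). Near-identical members of these families share reads, so values of single genes are uncertain. The 23 listed genes held a small part of the FPKM of a library. Over all libraries, other genes with the GO term nutrient reservoir activity summed to 10359.9 to 33294 FPKM and lipid transfer proteins to 32384.9 to 84589.5 FPKM.

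Alpha gliadins, another major gluten fraction, were not called as a list. In strong seed 5 of 8 genes had a higher mean, with a median log2 difference of 0.64 (camera adjusted p = 0.47), 0 called over all genes and 1 adjusted over the list alone. An alpha-amylase/trypsin inhibitor CM3 gene (MSTRG.32146, 4BL), the tested member of its list, averaged 8.95 ± 4.81 FPKM in strong and 2.20 ± 2.53 FPKM in weak seed (SD, n = 3). It passed only without weak replicate 1 (limma adjusted p = 0.145 with all libraries, 0.0314 at the lowest). Serpin-Z1C (MSTRG.38096, 5AL), a grain protease inhibitor, averaged 14.6 ± 12.01 and 1.47 ± 1.24 FPKM and did not pass (adjusted p = 0.354). None of the 3 tested serpins was called. The 1 tested globulin storage protein gene, Globulin 1 (MSTRG.3427, 1BL), had 0, 4.91 and 33.9 FPKM in strong and 9.73, 0.57 and 4.09 FPKM in weak seed and did not pass (adjusted p = 0.955). Its log2 difference of 0.42 ± 1.49 turned negative with a pseudocount of 0.1, without strong replicate 3, without weak replicate 2 and without the second libraries of all classes.

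**Figure D2:**
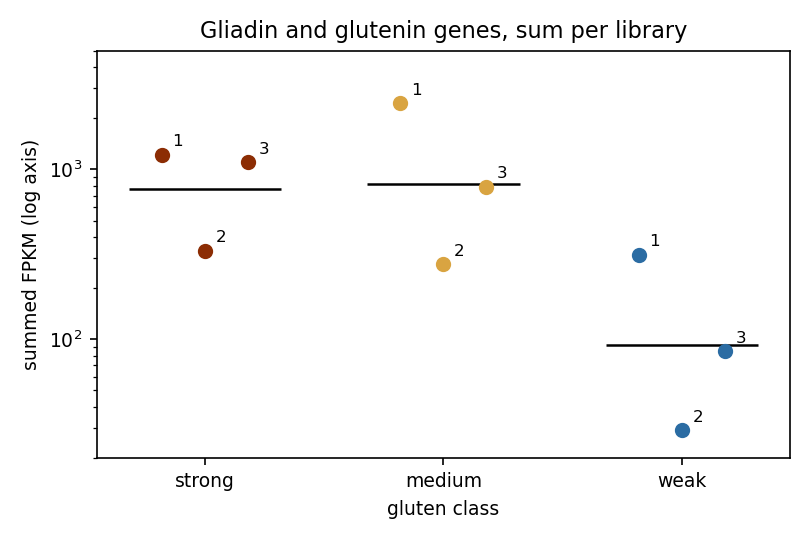
Summed FPKM of the 23 gliadin and glutenin genes in each library (vertical log axis, FPKM) by gluten class. Points are libraries with their replicate number, lines are means of log2(FPKM + 1) turned back to FPKM, and the 3 weak libraries, at 314, 29.2 and 84.9 FPKM, lie below the strong libraries, at 1219, 332 and 1106 FPKM.

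Among the described genes with the largest folds under the naming rule, which leaves out low and overlapping genes, a nucleoside diphosphate kinase (MSTRG.6233, 1DL), an enzyme that balances nucleotide triphosphates, averaged 23.1 ± 3.65 FPKM in strong and 1.91 ± 0.425 FPKM in weak seed (log2 difference 3.05 ± 0.23). A subunit of the oligosaccharyltransferase that glycosylates proteins in the endoplasmic reticulum (MSTRG.17288, 2DL) averaged 5.48 ± 0.333 and 0.12 ± 0.0265 FPKM (2.53 ± 0.16). An rRNA N-glycosidase (MSTRG.43236, 5DL), of the ribosome-inactivating protein family, had 76.2, 18.4 and 203 FPKM in strong seed and 0, 5 and 3.41 FPKM in weak seed. A glycosyltransferase (MSTRG.14397, 2BS) had 15.6, 16.0 and 9.47 FPKM and was listed at 0 in all weak libraries. On the lower side, a transcription elongation factor 1 homolog (MSTRG.25517, 3DL) averaged 0.387 ± 0.566 FPKM in strong against 17.8 ± 1.99 FPKM in weak seed (-3.83 ± 0.28). Clathrin light chain (MSTRG.59776, 7DL), part of the coat of transport vesicles, averaged 0.377 ± 0.0902 against 16.3 ± 1.48 FPKM (-3.65 ± 0.19). A glycosyltransferase on an unplaced scaffold (MSTRG.63162) averaged 0.0433 ± 0.0231 against 12.3 ± 6.68 FPKM (-3.56 ± 0.29), and a peroxidase (MSTRG.19560, 3AL) 1.93 ± 1.37 against 32.5 ± 19.0 FPKM (-3.46 ± 0.47). Their limma adjusted p ran from 7.8e-07 for WAMP-1 to 0.0253 for MSTRG.43236.

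Genes for starch synthesis did not move as a list (camera adjusted p = 0.47). Of 21 genes 3 had a higher mean in strong seed, the median was -0.18, and 2 were called, both lower, against 3 adjusted over the list alone. The called gene for chloroplastic pullulanase 1 (MSTRG.55937, 7AS), a starch-debranching enzyme, had 0.06, 0 and 0.01 FPKM in strong and 2.01, 3.42 and 1.17 FPKM in weak seed (adjusted p = 0.00535). Of 49 genes matched as defence proteins 2 were called, both lower, as were 2 adjusted over the list alone. Defensin-like protein 8 (MSTRG.40808, 5BL) averaged 351 ± 120 FPKM in strong and 1971 ± 1033 FPKM in weak seed (-2.37 ± 0.46). A second gene of that description (MSTRG.42931, 5DL) was the more abundant, at 4538 ± 1505 and 3147 ± 528 FPKM, and did not pass (adjusted p = 0.583). Of 79 cell cycle and histone genes 3 were called higher and 3 lower, and 10 passed adjusted over the list alone. The histone H2A gene MSTRG.15240 (2BS) averaged 2.14 ± 0.784 against 14.0 ± 3.14 FPKM (-2.26 ± 0.29).

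Markers of tissues other than starchy endosperm did not move as lists. In the photosynthesis list 1 of 6 genes was called higher, a chlorophyll a-b binding protein (MSTRG.44682, 5DL) at 1.99 ± 0.26 against 0.267 ± 0.0513 FPKM (log2 difference 1.23 ± 0.17), and 1 adjusted over the list alone. Of 19 embryo and oil body genes 0 were called, of 52 aleurone and germination genes 1 higher and 3 lower, and of 9 root or vegetative shoot genes 0, against 0, 7 and 1 adjusted over the list alone. A cysteine protease of the aleurone list (MSTRG.13479, 2BL) averaged 1.32 ± 0.778 FPKM in strong and 5.76 ± 1.66 FPKM in weak seed (-1.56 ± 0.32, limma adjusted p = 0.0186). This gene also carries the GO term for autophagy, so its match by words does not show that it marks aleurone. Lists with 0 calls were sucrose cleavage and sugar transport (26 genes), protein folding in the endoplasmic reticulum (20), nitrogen assimilation (32), dehydrins (5) and heat shock proteins (15). Adjusted over the list alone, 2 heat shock genes and 0 of the others passed. Of 22 lipid transfer proteins 1 was called higher, of 178 ribosomal proteins 2 higher, and of 103 peroxidase, glutathione and redox genes 1 higher and 1 lower. Adjusted over the list alone, 1, 0 and 1 passed. The called lipid transfer protein (MSTRG.66572, 3B) had 2.27, 4.16 and 4.16 FPKM in strong and 1.18, 0 and 0 FPKM in weak seed (limma adjusted p = 0.0187). The 40S ribosomal protein S27 gene MSTRG.54696 (7AL) averaged 43.1 ± 6.03 against 20.4 ± 4.85 FPKM (1.06 ± 0.26, 0.0442). Camera adjusted p of all lists not called was 0.136 or more. Camera compares a list with all other genes, whose median difference was -0.11 here. For dehydrins, ribosomal proteins, redox genes and lipid transfer proteins it pointed up while median and mean were negative. For aleurone genes the median alone was negative, and for defence genes the mean alone.

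Over all 40185 genes, 5654 had an unadjusted p under 0.05, and the libraries of the 2 classes did not overlap in 18.6% of genes, against 10% by chance. Leaving out any strong or weak library with the filter applied to the libraries left gave between 1158 and 1444 called genes, and between 1698 and 2080 with the same genes tested. The calls of MSTRG.43236 (without strong replicate 1 or 3 or weak replicate 1 or 3), MSTRG.14397 (strong 1), MSTRG.5989 (strong 1 or 3 or any weak library) and MSTRG.40808 (strong 1 or 2 or weak 1 or 2) were lost when such a library was left out. Their adjusted p reached 0.109, 0.123, 0.0902 and 0.189 over all alternatives. A pseudocount of 0.1 or a filter of 5 FPKM ended the call of MSTRG.43236, and testing without a filter or with the 2 classes alone those of MSTRG.43236 and MSTRG.40808. Leaving out all second libraries ended those of MSTRG.14397, MSTRG.5989, MSTRG.40808 and MSTRG.55937, and with the filter applied anew that of MSTRG.44682. The call of MSTRG.54696 was lost without any single library, with a filter of 5 FPKM, with TPM and with the 2 classes alone (adjusted p of up to 0.196). Those of MSTRG.66572 (strong 2 or 3 or weak 2 or 3) and MSTRG.13479 (strong 2 or 3 or weak 1 or 2) were lost without such a library and without the second libraries of all classes (up to 0.265 and 0.174).

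Strong against medium gluten set the upper classes of the trait side by side. WAMP-1 (MSTRG.16330) was again the gene with the largest fold among those named by the rule, with 0, 0 and 0.27 FPKM in medium seed. Caleosin (MSTRG.13313, 2BL), a protein of oil bodies, averaged 39.6 ± 23.4 FPKM (SD, n = 3) in medium seed against 415 ± 128 FPKM in strong seed. S-adenosylmethionine synthase 4 (MSTRG.51309, 6BS) had 0.04, 0 and 0.01 FPKM against 35.6, 22.3 and 20.8 FPKM. Pathogenesis-related protein 1-1 (MSTRG.39625, 5BL), an antimicrobial defence protein, had 36.3, 43.6 and 26.9 FPKM in medium seed and was listed at 0 in all strong libraries. Gliadin and glutenin totals, at 2462, 278 and 791 FPKM in the medium libraries, differed from strong seed by a log2 of -0.09 ± 1.09 (exact two-sided permutation test, p = 1). In all, 842 genes were higher and 1108 lower in strong seed.

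Oleosin (MSTRG.18688, 3AL), the main coat protein of oil bodies, had 609, 452 and 817 FPKM in strong and 5.69, 4.65 and 213 FPKM in medium seed (log2 difference 4.92 ± 1.16, limma adjusted p = 0.0422). The third medium library lay far above the other 2. Caleosin (3.54 ± 0.55, adjusted p = 0.00407) and oleosin were the 2 called genes of the 19 in the embryo and oil body list, 2 also adjusted over the list alone. The list was not called (median 0.08, camera adjusted p = 0.255). Urease accessory protein G (MSTRG.63454, unplaced scaffold) averaged 15.7 ± 8.81 against 0.81 ± 0.39 FPKM (3.11 ± 0.34), and a PsbP domain protein of the chloroplast (MSTRG.26113, 3DL) 25.3 ± 6.48 against 2.18 ± 0.552 FPKM (3.03 ± 0.55). Clathrin light chain (MSTRG.59776) was lower in strong than in medium seed too, where it averaged 12.7 ± 1.17 FPKM (-3.32 ± 0.19). GTP cyclohydrolase 1 (MSTRG.15602, 2DL), which opens folate synthesis, averaged 1.01 ± 0.164 against 15.5 ± 1.503 FPKM (-3.04 ± 0.42). A peptidyl-prolyl cis-trans isomerase (MSTRG.14804, 2BS), a folding enzyme, averaged 1.49 ± 0.59 against 18.3 ± 0.865 FPKM (-2.98 ± 0.23). A protein of the minor spliceosome (MSTRG.15838, 2DL) averaged 0.26 ± 0.151 against 5.64 ± 0.668 FPKM (-2.40 ± 0.27), and a DETOXIFICATION family transporter (MSTRG.63172, unplaced scaffold) had 2.25, 0 and 0 FPKM against 12.7, 9.83 and 18.1 FPKM.

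Sucrose cleavage and sugar transport was the called list (camera adjusted p = 0.0141). In strong seed 20 of its 26 genes had a higher mean, with a median log2 difference of 0.31, 0 genes called over all genes and 0 adjusted over the list alone. With an estimated correlation its adjusted p = 0.998, and without the low-value filter the median was near 0 (adjusted p = 0.406). The call was also lost with TPM and without strong replicate 1 with the same genes tested (adjusted p = 0.145 and 0.0981), where the medians were 0.16 and 0.19. Its most abundant members did not pass. A sucrose synthase (MSTRG.35186, 4DL) averaged 23.9 ± 6.16 in strong and 20.7 ± 11.7 FPKM in medium seed (limma adjusted p = 0.873). A SWEET sugar transporter (MSTRG.55557, 7AS) averaged 17.6 ± 5.66 and 14.1 ± 8.22 FPKM (0.886). The sign of the former turned without medium replicate 2 and that of the latter without medium replicate 1.

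No gluten list was called (camera adjusted p = 0.498 for LMW glutenins and 0.998 for the others). LMW glutenins (3 of 5 higher), alpha gliadins (4 of 8) and gamma gliadins (1 of 5) had median differences of 0.99, 0.15 and -0.40, with 0 genes called over all genes or adjusted over the list alone. Calreticulin-3 (MSTRG.18900, 3AL), a folding chaperone, was the called gene of 20 in the protein folding list, 1 also adjusted over the list alone, at 4.89 ± 2.21 against 1.03 ± 0.238 FPKM (1.47 ± 0.34). Pullulanase 1 (MSTRG.55937) was the called gene of 21 for starch synthesis, 1 also adjusted over the list alone, at 2.77, 1.8 and 1.59 FPKM in medium seed (-1.56 ± 0.26). Of 79 cell cycle and histone genes 1 was called higher and 4 lower, 6 adjusted over the list alone. The histone H4 gene MSTRG.24020 (3B) averaged 0.07 ± 0.07 in strong and 2.24 ± 0.861 FPKM in medium seed (-1.56 ± 0.22). The ribosomal protein S24 gene MSTRG.20307 (3AL) was listed at 0 in the strong and weak libraries and at 2.24, 4.45 and 3.68 FPKM in the medium ones, as 1 of 2 called among 178 ribosomal protein genes. A peroxidase (MSTRG.25466, 3DL) averaged 5.58 ± 1.89 against 21.1 ± 7.55 FPKM (-1.73 ± 0.33), the called gene of 103 in the redox list. From each of these 2 lists 1 gene passed adjusted over the list alone.

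Aleurone and germination genes had 1 called higher and 1 lower of 52, and defence proteins 1 higher and 2 lower of 49, with 2 and 3 adjusted over the list alone. The higher one was S-adenosylmethionine synthase 4, matched only by the letters of its name, and without such matches 0 were higher and 2 lower of 13. The cysteine protease MSTRG.13479 averaged 5.58 ± 1.76 FPKM in medium seed (-1.52 ± 0.32, limma adjusted p = 0.0239). Its call was lost without strong replicate 2 or 3, medium replicate 1 or 3 or all second libraries, without a filter or with one of 5 FPKM, and with the 2 classes alone (up to 0.119). The other lists, nitrogen assimilation, photosynthesis, dehydrins, lipid transfer proteins, heat shock proteins and root or vegetative shoot, had 0 calls over all genes and 0 adjusted over the list alone. Camera adjusted p of all lists not called was 0.255 or more. Its direction was up with a negative median and mean for gamma gliadins, heat shock and ribosomal proteins, up with a negative median alone for redox and defence genes, and down with a positive median for starch synthesis.

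An unadjusted p under 0.05 was reached by 5125 genes, and 19.4% of genes had non-overlapping libraries, against 10% by chance. Leaving out any strong library or medium replicate 1 or 3 with the filter applied to the libraries left gave between 1036 and 1196 called genes, and leaving out any library with the same genes tested between 1401 and 2096. The calls of MSTRG.18688 (without any single library but medium replicate 3), MSTRG.26113 (strong 1 or 3 or medium 3), MSTRG.63172 (strong 2 or 3 or any medium library), MSTRG.18900 (strong 1 or 2, any medium library or weak 2) and MSTRG.25466 (strong 2 or medium 1 or 3) were lost when such a library was left out. Their adjusted p reached 0.285, 0.0607, 0.242, 0.343 and 0.0702 over all alternatives. A pseudocount of 0.1 or robust empirical Bayes ended the calls of MSTRG.18688 and MSTRG.63172, and testing without a filter or with one of 5 FPKM these and that of MSTRG.18900. Quantile normalization ended that of MSTRG.18688, median-of-ratios scaling and TPM that of MSTRG.63172, and the 2 classes alone those of MSTRG.18688 and MSTRG.18900. Leaving out all second libraries ended those of MSTRG.18688, MSTRG.63172, MSTRG.18900 and MSTRG.24020, and with the filter applied anew those of MSTRG.25466, MSTRG.26113 and MSTRG.55937.

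In medium against weak gluten, the 5 LMW glutenin and 5 gamma gliadin genes all had a higher mean in medium seed, with median log2 differences of 2.68 and 2.85, the former 1.69 without medium replicate 1 and 4.35 with a pseudocount of 0.1. Wheatwin-1 (MSTRG.19036), a pathogenesis-related protein of the grain, averaged 1587 ± 416 FPKM against 70.6 ± 80.1 FPKM in weak seed (SD, n = 3). The rRNA N-glycosidase gene MSTRG.43236 had 445, 100 and 95.5 FPKM in medium seed against 0, 5 and 3.41 FPKM. Agglutinin isolectin 2 (MSTRG.7595, 1DL), the wheat germ lectin, was listed at 0 in all medium libraries and at 304, 150 and 214 FPKM in the weak ones. In all, 968 genes were higher and 1211 lower in medium seed.

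Gliadin and glutenin totals differed by a log2 of 3.12 ± 1.33 between medium and weak seed (exact two-sided permutation test, p = 0.2), with 1 medium library, the second, at 278 FPKM, below the highest weak library at 314 FPKM. The difference ran from 2.31 without weak replicate 2 to 4.001 without weak replicate 1. The LMW glutenin list was called (camera adjusted p = 0.00419), with 1 gene called over all genes and 3 adjusted over the list alone. Its adjusted p = 0.62 with an estimated correlation. For the gamma gliadin list (camera adjusted p = 0.0295) 0 genes were called over all genes and 2 adjusted over the list alone, and its adjusted p = 0.573 with an estimated correlation. Its call was lost with a pseudocount of 0.1 (adjusted p = 0.0681), without weak replicate 2 or, with the same genes tested, medium replicate 3 (0.0959 at the highest). The LMW glutenin P3-6 gene (MSTRG.8042, 1DS) averaged 28.9 ± 25.7 against 1.66 ± 2.04 FPKM (3.34 ± 0.80, limma adjusted p = 0.0425). A pseudo alpha/beta-gliadin gene (MSTRG.47785, 6AS) averaged 42.8 ± 28.6 against 4.22 ± 4.89 FPKM (3.23 ± 0.80, 0.0495), the called gene of the 8 alpha gliadins, 1 also adjusted over the list alone. That list had a median of 0.94 and was not called (camera adjusted p = 0.476). The glutenin subunit gene MSTRG.8204 had 356, 33.9 and 84.3 FPKM in medium seed and did not pass (limma adjusted p = 0.0576), but did so with quantile normalization and without weak replicate 1 (0.0125 at the lowest). Gamma-gliadin 2 (MSTRG.8405) averaged 245 ± 274 FPKM in medium seed and did not pass either (0.192).

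Another 2 lists were called, both with a median below 0. Of 20 genes for protein folding in the endoplasmic reticulum 2 had a higher mean, with a median of -0.29 (camera adjusted p = 0.0295, and adjusted p = 0.62 with an estimated correlation). Calreticulin-3 (MSTRG.18900) was the called gene, 1 also adjusted over the list alone, with 5.58 ± 2.23 FPKM in weak seed (-1.65 ± 0.34). The abundant protein disulfide isomerases MSTRG.32872 (4BS) and MSTRG.8453 (1DS) averaged 58.5 ± 17.3 and 49.7 ± 3.92 FPKM in medium against 72.1 ± 17.9 and 61.2 ± 10.6 FPKM in weak seed without passing. Of 15 heat shock proteins 1 had a higher mean, with a median of -0.69 (camera adjusted p = 0.0421, and adjusted p = 0.93 with an estimated correlation), 0 called over all genes and 0 adjusted over the list alone. The median was -0.33 without medium replicate 2, -0.44 without weak replicate 3 and -0.41 without a filter. Its abundant members, the chloroplastic small heat shock proteins MSTRG.31222 (4BL) and MSTRG.34779 (4DL), ranged from 20.4 to 560 and from 10.97 to 438 FPKM within weak seed, and without weak replicate 3 the list's adjusted p was 0.71. The folding list lost its call with a pseudocount of 0.1, without all second libraries, without medium replicate 1 or 3 or strong replicate 1, and with the same genes tested without weak replicate 1 or 2 (0.0935 at the highest, with a median of -0.17 without weak replicate 1). The heat shock list lost its call also without any medium library or strong replicate 1, with a pseudocount of 0.1, without a filter or with one of 5 FPKM, and with TPM (adjusted p of 0.0813, 0.325, 0.116 and 0.0656).

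Another rRNA N-glycosidase gene (MSTRG.40958, 5BL) averaged 134 ± 121 against 7.57 ± 8.11 FPKM (log2 difference 4.03 ± 0.94), and pathogenesis-related protein 1-1 (MSTRG.39625) had 0, 6.74 and 0 FPKM in weak seed (limma adjusted p = 0.00433). Lower in medium seed were S-adenosylmethionine synthase 4 (MSTRG.51309), at 29.1, 24.0 and 22.7 FPKM in weak seed, and RABC1 (MSTRG.12562), at 0.0467 ± 0.0551 FPKM in medium seed (-4.04 ± 0.25). The elongation factor 1 homolog MSTRG.25517 averaged 0.25 ± 0.246 FPKM (-3.92 ± 0.28). HS1 (MSTRG.11385) averaged 0.807 ± 0.267 FPKM (-3.87 ± 0.27) and the glycosyltransferase MSTRG.63162 0.0533 ± 0.0252 FPKM (-3.55 ± 0.29). Caleosin (MSTRG.13313) was the called gene of 19 in the embryo and oil body list, at 362 ± 137 FPKM in weak seed (-3.30 ± 0.55), 2 genes passing adjusted over the list alone.

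For starch synthesis 1 of 21 genes was called, a glucose-1-phosphate adenylyltransferase (MSTRG.36520, 5AL), the enzyme that makes the sugar donor of starch, at 2.30 ± 0.216 against 0.69 ± 0.321 FPKM (0.98 ± 0.19). Of the 21, 4 had a higher mean and 2 passed adjusted over the list alone. The chlorophyll a-b binding protein MSTRG.44682 averaged 1.74 ± 0.363 FPKM in medium seed (1.11 ± 0.17), the called gene of 6 for photosynthesis, 1 also adjusted over the list alone. A carboxypeptidase (MSTRG.36201, 4DS) had 0.04, 0.19 and 0 FPKM in medium and 2.09, 2.18 and 2.58 FPKM in weak seed, among 3 of 52 aleurone and germination genes called, all lower, as were 3 adjusted over the list alone. The histone H2A gene MSTRG.54894 (7AL) averaged 0.713 ± 0.0862 against 6.95 ± 3.61 FPKM (-2.09 ± 0.36), in a list of 79 with 5 called higher and 2 lower, 7 adjusted over the list alone. Ribosomal proteins had 1 called higher, MSTRG.20307, and 1 lower, the redox list 1 lower, the peroxidase MSTRG.19560 (-3.07 ± 0.47), and the defence list 1 higher and 2 lower, with 1, 1 and 3 adjusted over the list alone. S-adenosylmethionine synthase 4 is counted there only because its name contains the letters of thionin. Sucrose cleavage and sugar transport, nitrogen assimilation, dehydrins, lipid transfer proteins and root or vegetative shoot had 0 calls over all genes and 0 adjusted over the list alone. Camera adjusted p of all lists not called was 0.101 or more, and its direction was down with a positive median for embryo and oil body genes.

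An unadjusted p under 0.05 was reached by 5401 genes, and 17.0% of genes had non-overlapping libraries, against 10% by chance. Leaving out medium or weak replicate 1 or 3 with the filter applied to the libraries left gave between 1214 and 1380 called genes, and leaving out any library with the same genes tested between 1689 and 2163. Over the 3 comparisons in the order above, 38.5%, 43.2% and 44.4% of called genes were higher in the class named first. The share was 42.9%, 44.1% and 47.3% with median-of-ratios scaling and 45.4%, 46.9% and 47.3% with quantile normalization. With a library left out and the filter applied anew, this share ran from 26.5% (without strong replicate 1) to 53.2% (weak 1), from 31.7% (strong 1) to 58.6% (medium 3) and from 31.3% (medium 3) to 60.8% (weak 1). Such a filter drops genes present in the shortened class alone. With the same genes tested the lower side stayed the larger in every refit. The calls of MSTRG.19036 (without any medium library or weak 1 or 3), MSTRG.40958 (strong 1, any medium library or weak 2 or 3), MSTRG.8042 and MSTRG.47785 (both strong 1 or 3, medium 1 or 3 or weak 2 or 3), MSTRG.7595 (any medium or weak library), MSTRG.18900 (any medium library or weak 1 or 2) and MSTRG.36520 (medium 3 or weak 1 or 2) were lost when such a library was left out. Their adjusted p reached 0.13, 0.156, 0.158, 0.2, 0.202, 0.181 and 0.181 over all alternatives. Testing without a filter or with one of 5 FPKM, or robust empirical Bayes, ended the first 5 of these calls, and the filter of 5 FPKM that of MSTRG.18900. A pseudocount of 0.1 or the 2 classes alone ended those of MSTRG.8042 and MSTRG.47785, TPM that of MSTRG.47785 and median-of-ratios scaling that of MSTRG.7595. Leaving out all second libraries ended those of MSTRG.19036, MSTRG.40958, MSTRG.7595, MSTRG.18900 and MSTRG.36520, and with the filter applied anew those of MSTRG.8042 and MSTRG.47785.

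**Figure D3:**
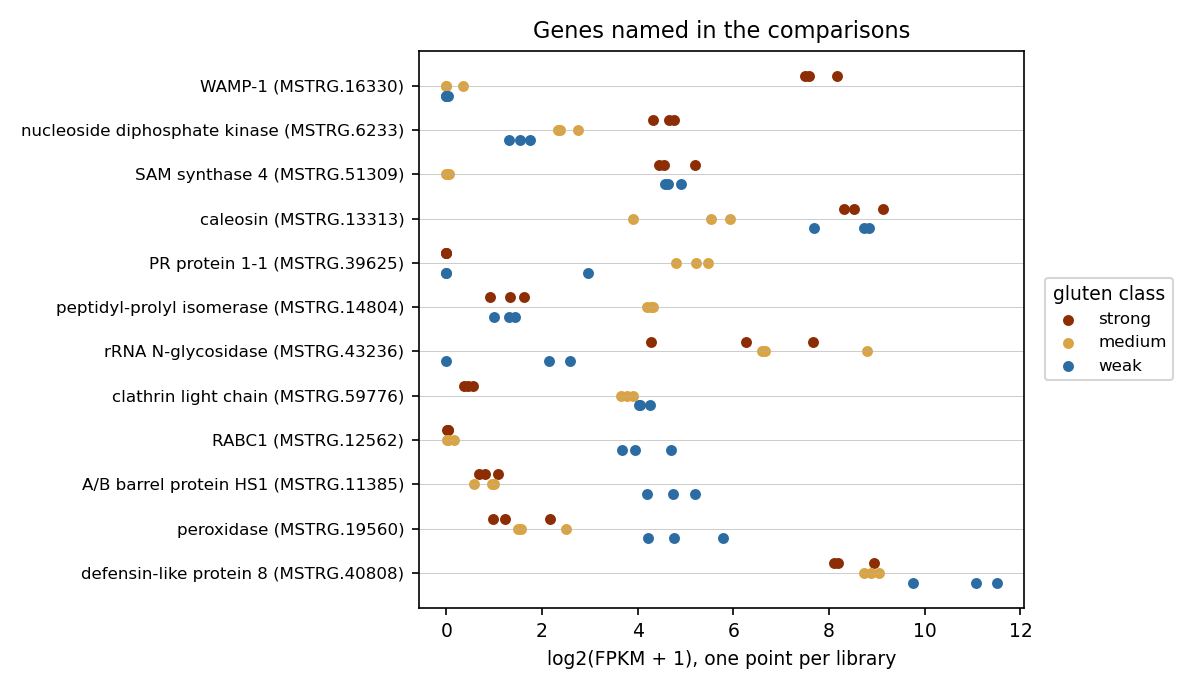
Values of 12 genes named in the comparisons, as log2(FPKM + 1) on the horizontal axis, with a point per library and colours for the gluten classes. WAMP-1 is high in the 3 strong libraries alone, at 179 to 286 FPKM, and RABC1, HS1, peroxidase and defensin-like protein 8 are highest in the 3 weak libraries.

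Genes in which a single class stood apart from both others included many of those named above. Apart in strong seed were 844 genes, 357 higher and 487 lower than in both other classes, WAMP-1 (MSTRG.16330) and the nucleoside diphosphate kinase MSTRG.6233 being among the higher and clathrin light chain (MSTRG.59776) and pullulanase 1 (MSTRG.55937) among the lower. Apart in medium seed were 798 genes, 415 higher and 383 lower, with pathogenesis-related protein 1-1 (MSTRG.39625) and the ribosomal protein S24 gene MSTRG.20307 higher and caleosin (MSTRG.13313) and S-adenosylmethionine synthase 4 (MSTRG.51309) lower. Apart in weak seed were 994 genes, 624 higher and 370 lower, with RABC1 (MSTRG.12562), HS1 (MSTRG.11385), the elongation factor 1 homolog MSTRG.25517 and the peroxidase MSTRG.19560 higher and the chlorophyll a-b binding protein MSTRG.44682 lower. The 2 comparisons behind each count share 3 libraries. With simulated unchanged libraries at most 1 gene stood apart. No gene differed between classes there, so this gives only the rate of false calls. Independent lists of these sizes would share 17.7 higher and 37.2 lower genes for strong, 26.7 and 25.4 for medium and 40.7 and 20.4 for weak seed. With 3 shared libraries, too few to split, part of the excess may come from sharing them. A gene that differs in a single class also tends to be called in both of its comparisons. Neither value is therefore a chance level for these counts. Without medium replicate 1 and with the filter applied to the libraries left, 300 genes stood apart in medium seed, and likewise 351 in strong seed without strong replicate 1 and 342 in weak seed without weak replicate 1.

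Of the genes called between strong and weak seed, 1134 (51.6%) had a medium mean between the other 2 class means, 374 of them higher in strong and 760 higher in weak seed. Among genes not called the share was 33.0%, and 33.3% would follow if each of the 3 class means were equally often in the middle. Called genes are chosen for strong and weak means far apart, which by itself leaves more room between them, so these shares do not measure an excess of grading. The nucleoside diphosphate kinase MSTRG.6233, at 4.64 ± 0.935 FPKM in medium seed (SD, n = 3), and the histone H2A gene MSTRG.15240, at 8.16 ± 2.40 FPKM, were of this kind. Only 17 genes were called in the same direction in all 3 comparisons. Without weak replicate 1 and with the filter applied to the libraries left, the graded count was 607.

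Some genes were present in every library of 2 classes, at 1 FPKM or more, and at 0.1 FPKM or less in every library of the third, the pattern that a missing or diverged chromosome segment would leave. There were 150 such genes for strong, 133 for medium and 91 for weak seed, of 22582, 22137 and 22133 genes that met the first condition, and 209 of the 374 (55.9%) had no gene name. The short arm of chromosome 1B, exchanged with rye in many cultivars, held 0 of 222, 2 of 212 and 1 of 216 such genes. No chromosome arm passed against the rest of the genome (Fisher's exact test, two-sided, lowest adjusted p of a named arm 0.238). Among genes with a known arm alone, a test added later, the lowest adjusted p was 0.205, for 1DL in medium (8 of 621) and 2BS in weak seed (5 of 413). No arm held more than 8 such genes, so a difference between arms is not excluded. Unnamed loci differed from the rest, with 3.32% of 3132 loci in strong, 2.06% of 2966 in medium and 1.46% of 3021 in weak seed (adjusted p = 2.44e-52, 4.79e-18 and 7.63e-14).

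Except for S-adenosylmethionine synthase 4, the most abundant genes of this kind have no description in the files. Silent in strong seed were MSTRG.58436 (7BL), listed at 0 there and at 12.8, 2.73 and 12.8 FPKM in medium and 69.8, 75.3 and 57.7 FPKM in weak seed, and 2 others. The unnamed locus MSTRG.18607 was listed at 0 against 33.1, 34.2 and 36.1 and then 48.2, 58.6 and 19.3 FPKM. MSTRG.50094 (6BL) had 0.02, 0 and 0 FPKM against 45.8, 13.1 and 70.6 and then 102, 14.5 and 4.79 FPKM. Silent in medium seed were S-adenosylmethionine synthase 4 (MSTRG.51309) and MSTRG.13212 (2BL), at 13.5, 26.4 and 43.8 FPKM in strong and 40.4, 21.7 and 40.6 FPKM in weak seed. In medium seed the unnamed locus MSTRG.44150 was listed at 0, 0 and 0.03 FPKM against 23.4, 11.8 and 26.5 and then 44.0, 7.95 and 46.4 FPKM. In weak seed MSTRG.7926 (1DS) was listed at 0, against 65.7, 42.2 and 100.4 FPKM in strong and 66.2, 14.9 and 83.8 FPKM in medium seed. The unnamed locus MSTRG.2145 had 0.01, 0.02 and 0.07 FPKM in weak seed against 63.2, 3.81 and 45.6 and then 179, 26.9 and 52.4 FPKM. MSTRG.2610 (1AS) had 0, 0 and 0.1 FPKM against 4.17, 8.18 and 6.08 and then 44.9, 27.1 and 76.3 FPKM. The strong against weak calls of MSTRG.50094 and MSTRG.2145 were lost without any strong library or weak replicate 2, and without strong replicate 1 or 3 or any weak library (adjusted p of up to 0.143 and 0.0971). The strong against medium call of MSTRG.50094 was lost without strong replicate 3 or medium replicate 1 or 3 (up to 0.0756). Testing without a filter ended both strong against weak calls, and leaving out all second libraries both calls of MSTRG.50094, whose strong against weak call was also lost with the 2 classes alone.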

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

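Leaving out libraries with the genes tested kept, leaving out all second libraries, leaving out isolated zeros, correcting lists and adding the GO list were chosen only after the results were seen. Depth is unknown, so what depth limits cannot be stated. Of 2547 refits of the 87 gene results listed from the text, 2216 kept direction and side of the threshold, 307 in 27 results fell short of it, 13 in 5 results newly passed it and 11 in 3 results, none past the test, turned sign. The sucrose synthase MSTRG.35186 turned to -0.10 without medium replicate 2 (0.72 at the highest) and the SWEET gene MSTRG.55557 to -0.0028 without medium replicate 1 (0.80 at the highest). Globulin 1 (MSTRG.3427) turned to -0.23 with a pseudocount of 0.1, -0.86 without strong replicate 3 and -0.32 without weak replicate 2 or all second libraries (1.70 at the highest). Counts of called, apart and graded genes stayed within 1.5 times under a pseudocount of 0.1, no filter, both scalings, TPM, robust empirical Bayes and without isolated zeros, and called genes also with the 2 classes alone and at a log2 change of at least 1. At the preset correlation the LMW glutenin lists were called in all 28 refits of each comparison (highest adjusted p 0.0138 and 0.0366), but not with an estimated correlation (0.45 and 0.62) or fry. The gamma gliadin lists were called in 16 and 18 of 22, sugar genes in 26, folding genes in 20 and heat shock genes in 17 of 29.

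With a filter of 5 FPKM, which left 12064 genes to test, 437, 391 and 424 genes were called for strong against weak, strong against medium and medium against weak. Apart were 179, 159 and 186 in strong, medium and weak seed, 248 were graded and 1, 2 and 2 lists were called. Lists called in the main analysis were 2, 1 and 4. They became 1 and 1 in the first and last comparison with a pseudocount of 0.1, and 1 in the first with median-of-ratios scaling and with quantile normalization. They became 0 in the second without a filter and with TPM. The cause of these changes was not tested. They became 0 and 2 in the first and last without isolated zeros, since too few LMW glutenin and gamma gliadin genes were left for these lists to be tested. With an estimated correlation they were 0, 0 and 0, and with fry 0, 0 and 0. Silent genes, 374, became 225 at exactly 0 FPKM, 558 at up to 0.5 FPKM and 23 with presence at 5 FPKM. They were 568 with TPM and 564 without all second libraries, where fewer libraries have to agree.

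Without the second library of every class and with the genes tested kept, 1609, 1377 and 1622 genes were called, 526 stood apart in medium seed, and 4, 3 and 3 lists were called. With the filter applied to the 6 libraries left, by which genes present in a single class cannot pass, 654, 612 and 657 genes were called of 36187. Apart were 253, 193 and 221 in strong, medium and weak seed, 396 were graded and 5 lists were called for strong against medium. Leaving out a single library with the filter applied anew, and then with the genes tested kept, gave 1158 to 2208 and 1698 to 2221 called genes for strong against weak, 1036 to 2052 and 1401 to 2096 for strong against medium, and 1214 to 2079 and 1689 to 2163 for medium against weak. Apart were 351 to 819 and 635 to 861 in strong, 300 to 751 and 592 to 790 in medium, and 342 to 879 and 782 to 967 in weak seed. Graded were 607 to 1038 and 843 to 1123. Lists in both versions were 1 to 4, 0 to 3 and 1 to 4, and silent genes 397 to 431.

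The labels do not say whether equal replicate numbers mark a shared field, day or batch, and the data leave pairing open. Same-numbered libraries of different classes had correlated deviations of 0.00686 to 0.265, all above 0 and above 0.1 in 2 of 9 pairs. Of the 9 libraries 7 were closest to one of their own number, a hint from the data alone. In all 3 classes the second library had the lowest gliadin and glutenin total. The main fit and the permutation tests of totals ignored replicate number. With the replicate number as a block, 2115, 1857 and 2118 genes and 2, 1 and 4 lists were called, 821, 746 and 938 genes stood apart and 1097 were graded, all within 1.5 times. The glutenin subunit MSTRG.8204 and gamma-gliadin 2 (MSTRG.8405) passed in both comparisons with weak seed (highest limma adjusted p 0.0449), and the ribosomal protein gene MSTRG.54696 lost its call.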

Other observations

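The tests by GO term, chromosome arm and genome copy, and in the weighing below the tests on the sum of 3 copies, on the level of the called copy, on the LMW glutenin scaling, on summed FPKM and on starch genes, were chosen only after the results were seen. Among genes higher in medium than in weak seed, 5 GO terms were over-represented (Fisher's exact test, adjusted over 904 terms). Genes with rRNA N-glycosylase activity, which stop ribosomes, were called higher in 4 of 13 cases (adjusted p = 0.00282), the same 4 genes carrying the term for negative regulation of translation. Inhibitors of endopeptidases were called higher in 8 of 91 cases (adjusted p = 0.00282), and genes for protein heterodimerization in 11 of 139 (adjusted p = 0.000739), against 1.18% of all annotated genes. The nucleosome term, with 6 of 110 genes called higher, did not pass (adjusted p = 0.222). No term passed in the other directions and comparisons. Genes with the GO term nutrient reservoir activity, which adds cupins and other storage proteins to the gliadins, had a median log2 difference of 0.43 for medium against weak seed over 57 genes (camera adjusted p = 0.00885, and adjusted p = 0.80 with an estimated correlation) and 0.31 for strong against weak (camera adjusted p = 0.0157, and adjusted p = 0.902 with an estimated correlation). Without gliadins and glutenins, the summed FPKM of that term differed between medium and weak seed by a log2 of 0.92 ± 0.36 (exact permutation test, p = 0.1) and between strong and medium seed by -0.77 ± 0.25 (p = 0.1), the smallest p possible, but between strong and weak seed by only 0.15 ± 0.39 (p = 0.8), while gliadin totals of strong and medium seed differed by -0.09 ± 1.09.

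Called genes were unevenly spread over chromosome arms. Of 596 tested genes on 2AS, 50 were higher in weak than in strong seed (8.39% against 2.07% elsewhere, adjusted p = 5.50e-14) and 50 higher in weak than in medium seed (8.39% against 2.04%, adjusted p = 4.78e-14), HS1 (MSTRG.11385) among them, while 13 on this arm were higher in medium seed. Arm 2DL, with GTP cyclohydrolase 1 (MSTRG.15602), had 68 of 971 genes lower in strong than in weak seed and 42 lower than in medium seed (adjusted p = 9.77e-15 and 1.33e-06), and 1DL had 45 of 978 genes higher in strong than in medium seed and 51 lower in medium than in weak seed (adjusted p = 1.46e-09 and 3.74e-07). Genes of the D genome were called less often than those of A and B, at 2.21%, 2.31% and 2.32% in the 3 comparisons, and those of the B genome more often, at 4.87%, 4.26% and 5.06% (Fisher's exact test, highest adjusted p 5.01e-10). Without 1DL and 2DL the D shares were 1.69%, 1.52% and 1.80%.

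All tested LMW glutenin and gamma gliadin genes had a lower mean in weak than in strong seed, while alpha gliadins were not called and both list calls were lost with an estimated correlation. For gamma gliadins the list call does not survive other scalings: the mean log2 difference was 2.16 ± 0.88 as deposited, 2.20 ± 0.85 with median-of-ratios scaling and 2.23 ± 0.89 with quantile normalization, yet the adjusted p of the list went from 0.0224 to 0.0919 and 0.1364, for a reason not tested. The LMW glutenin call is not a product of scaling, with a highest adjusted p of 0.0009256 and a mean log2 difference of 3.38 ± 0.80 before and 3.43 ± 0.74 after quantile normalization. Unequal division of reads among the 23 listed gliadin and glutenin genes would leave their sum level. The sum differed by a log2 of 3.033 ± 1.15 (SE). Reads shared with unlisted or unnamed copies would change it, so such division stays open. Within classes, unnamed FPKM share and log2 total had a Pearson r of -0.754 (exact permutation test, p = 0.037) and a Spearman rho of -0.617 (p = 0.111). A smaller share of starchy endosperm in weak seed would lower starch synthesis genes with the gliadins. Their median difference, strong minus weak, was -0.1796, and per-library medians differed by -0.209 ± 0.130 (SE between libraries), far under the 0.5 set for that cause. Of 21 genes 2 were called, both lower in strong seed. The list summed to 54.8 to 94.4 FPKM per library and was not shown to track starchy endosperm, so that cause is not excluded. Seed stage, growing place, genotype and the class difference in gluten itself stay open as untested explanations, and both list calls rest on few genes, 11 of the 18 tested gliadin and glutenin genes having an isolated 0.

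Copies were taken as 3 tested genes with the same description, 1 on each of the A, B and D genomes of a chromosome group. No sequences were compared, and 697 such triads were found. Triads called in more than 1 comparison numbered 56, so the 139 cases pooled below are not independent. Where a called gene had such copies, the change of the others was taken from their summed FPKM, whose sign an abundant copy can set alone. The summed other copies moved the opposite way in 24 of 51 triads for strong against weak (47.1%, against 29.1% where no copy was called, Fisher's exact test, p = 0.0108), 17 of 41 for strong against medium (41.5% against 35.5%, p = 0.502) and 26 of 47 for medium against weak (55.3% against 34.8%, p = 0.00696), comparisons that share triads and libraries. Reads wrongly reassigned between copies may cause this, but as the whole change it would leave the sum of the 3 copies level, and over all 139 cases the sum moved with the called copy by a median log2 of 0.4476 ± 0.0255 (bootstrap SE). As a part of the change it cannot be told apart, since the summed partners had a median of 0.01566 ± 0.0388, within its error of both 0 and a small fall. Nor is a low level decided: in triads of at least 5 FPKM in all the share was 49.25%, under the 50% set for that cause but with a 95% interval of 40.5 to 58.0, and for called copies of at least 5 FPKM it was 70.6%, 63.6% and 64.7%, against 30.5%, 35% and 36.4% without a call (Fisher's exact test, p = 0.00209, 0.06184 and 0.0360), more often opposite but not past 0.05 in every comparison. Sequence differences between the classes and the reference, and balanced regulation of copies, stay open and untested.

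Assembled loci without a gene name made up a large part of the class-dependent genes: 19.995% of them were called in some comparison, against 6.24% of named genes. A lower level of such loci is not the whole reason, since named genes of matched level were called in 9.54%, a ratio of 2.095 (95% interval 1.96 to 2.23). It may be a part, as matching raised the share of named genes from 6.24%. Of 222 unnamed loci low in 3 libraries and present in the other 6, 209 were low in a whole class, 26.36 times the 7.93 expected. For these loci, this argues against estimates failing at random in single libraries. Loci low in fewer libraries were not counted, so random failure as a reason for the excess of called loci cannot be decided. As a hypothesis, part of these loci may be sequence carried by some of the classes and not by others. No genome was used here, so this and an assembly step that joins or splits loci by library stay open.

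Other splits of the same libraries bear on whether chance can be excluded. For called genes, the 10 splits of 6 libraries are too few for a share under 0.05; the real split gave 2196, 1950 and 2179 genes and was the only 1 of 10 with so many each time, the highest other splits giving 6, 6 and 7. For lists called by camera at its preset correlation, 9, 10 and 7 of 10 splits, the real one included, gave as many lists as the 2, 1 and 4 found, with 5, 6 and 5 at the highest. The number of lists called was thus no larger than regrouped libraries gave, so chance is enough to account for it. These splits compared counts only, not which lists were called. Of 100 splits of the 9 libraries into 3 classes, 2 gave as many genes apart as the 844 of strong seed, the other being the weak libraries under another name with 994, and 1 each as many as the 798 of medium and the 994 of weak seed, the highest others being 561 and 844, the latter the strong libraries under another name. For graded genes 1 of 100 splits gave as many as 1134, the highest other giving 438. A random assignment of libraries to classes can thus be excluded as the source of the apart counts and of the number of graded genes. Splits of 6 libraries that mix classes called at most 7 genes, while other splits of the 9 libraries reached 561 genes apart and 438 graded. Both results show only that the classes separate. Neither tests grading or an excess of genes in which a single class stands apart.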
